A study of Mus musculus with 8 samples.

How the data were processed

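Messenger RNA was sequenced from 8 libraries of embryonic mouse cortex that make up 2 separate experiments. In the knockdown experiment, plasmids at 3 µg/µl, either a control or one expressing a short hairpin RNA (shRNA) against the long noncoding RNA Lockd, were introduced by in utero electroporation into brains of ICR embryos at E14.5 (embryonic day), and GFP-positive cells were sorted at E16.5. In the knock-in experiment, whole cortices of C57BL/6 wild-type and PlyA-KI embryos were dissected at E13.5 and pooled. The labels do not spell out the PlyA-KI allele, so it is named here only by its label. Each of the 4 groups holds 2 libraries that the labels call biological replicates. Litters, and the number of embryos behind a library, are not given in the sources used here, so p-values measure only the spread between these libraries. Per the labels' protocols, total RNA was extracted with TRIzol, messenger RNA was captured and fragmented, and libraries were made with the KAPA Hyper Prep kit.

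Per the submitters' processing notes, bcl2fastq, Trimmomatic, HISAT2 and featureCounts were used with the mm10 build. Their versions, the annotation and the strand setting of the counting are not given in the sources used here, so values of genes that overlap each other or have an antisense partner are uncertain, as are those of genes with near-identical copies. The authors deposited, for each library, the count of reads per gene as whole numbers that were not normalised. Beside each count the authors deposited an FPKM value, the count scaled by the length of the gene in kilobases and by the total count of the library. The gene length that these FPKM values imply was a whole number, within a tolerance of 0.001, for 100% of genes.

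The tables list 27178 genes by Entrez identifier. Of these, 25274 were named through the RefSeq gene table of assembly GRCm38.p6 and 18 through the GENCODE annotation supplied with the reference. The 1886 identifiers without a name stayed in all tests under their number and held 0.423 to 0.968% of the counts of a library. Coordinates are those of GRCm38, counted from 1.

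Libraries held 12805874 to 15911118 counts in the knockdown experiment and 35167646 to 47460020 in the knock-in experiment. Levels are given as CPM, the count scaled to the deposited total of its library with no further factor, mean ± SD over 2 libraries. A limit of 3 counts equals 0.189 to 0.234 CPM in the first experiment and 0.063 to 0.085 CPM in the second. Molecular identifiers are not described in the sources used here, so such limits and intervals cover counting error only.

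Each experiment was fitted on its own 4 libraries with edgeR 4.0.16 in R 4.3.3: filterByExpr on low counts, TMM scaling (factors 0.993 to 1.013), the quasi-likelihood F-test (two-sided) and Benjamini-Hochberg adjustment with a threshold of 0.05. The filter left 13758 genes in the knockdown and 15398 in the knock-in experiment. The standard error of a log2 fold change was taken as its absolute value over the square root of its F statistic. Whether the 2 responses differ was tested as an interaction in one fit of all 8 libraries. The experiments share no library. Fold changes of genes tested in both were compared by Pearson's r and Spearman's rho across genes, which are not independent replicates.

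In addition, 34 gene lists were drawn up, covering the Lockd locus, the cell cycle, progenitors, neurons, signalling and stress pathways, and cell types or RNA that a sort or dissection can carry over. Each list with 5 or more tested members was tested with camera in limma 3.58.1 (a comparison with all other genes, preset correlation between genes 0.01, adjusted over the lists), and repeated with an estimated correlation and with fry, which asks whether a list's genes move, on balance, one way. Where list members are correlated well above the preset, camera's p with the preset is too small. For list members a second adjustment was made over the list alone. The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined.

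Under that rule, the genes named are Lockd, Cdkn1b and other detected genes of the locus; up to 10 called genes per direction with separated groups and a mean of 5 CPM or more, leaving out predicted and unnamed loci; 2 to 4 members of each list described, those with the smallest p; and all detected inhibitors of cyclin-dependent kinases (CDKs), D-type and E-type cyclins. With fewer than 5 calls, the 10 genes with the smallest p are named too. Where 5 or fewer members of a list passed the adjustment over the list alone, further ones are named, an addition made after their values were seen.

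Alternatives were DESeq2 size factors within edgeR, no filter on low counts, CPM of 1 or more in at least 2 libraries, one fit of all 8 libraries, the replicate number as a block, a minimum absolute log2 fold change of 1, the Wald test of DESeq2 1.42.0 (which gave no adjusted p to 3468 genes in the knockdown and 2687 in the knock-in, so that a count of 0 says nothing about these), limma-trend on the deposited FPKM as log2(FPKM + 1) or log2(FPKM + 0.1) for genes with FPKM of 1 or more in at least 2 libraries, and leaving out each library in turn. List tests on the interaction, leave-one-out values of the interaction and of the correlation, the overlap of genes at an unadjusted p under 0.05, the genes called in both experiments by DESeq2, the Lockd locus list without Lockd, and residuals after splines on transcript length, GC content and mean level were added after the data were seen.

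The main edgeR fit and DESeq2 were tested on simulated counts drawn from the real means and library sizes, with 200 genes changed, and camera on simulated lists. Each simulated gene took the dispersion of the fitted trend at its level, so differences in dispersion between genes of like level were left out. The recovered shares may therefore be too high for real genes. The interaction, fry, the replicate block, fits that leave out a library and the other alternatives were not simulated. For the knockdown design, edgeR recovered 20, 71.5 and 95.5% of genes changed 1.5-fold, 2-fold and 4-fold (13578, 13563 and 13592 genes tested). For the knock-in design the shares were 56, 73 and 96% (15223, 15214 and 15199 genes tested). False edgeR calls were 1 of 41, 6 of 149 and 8 of 199 in the knockdown design. In the knock-in design they were 4 of 116, 5 of 151 and 17 of 209. DESeq2 recovered 23.5, 69.5 and 89% in the knockdown design, with 4, 5 and 4 false calls. In the knock-in design it recovered 53, 74 and 91.5%, with 4, 5 and 10. A simulated list of 50 genes shifted 1.3-fold was called by camera in both designs and 0 of 30 unshifted lists were. With an estimated correlation the shifted list had a camera adjusted p of 0.163 in the knockdown design and 0.098 in the knock-in design. This stricter form thus missed a shift that was present. Simulated genes were drawn independently, so false calls by the preset form on lists of correlated genes were not tested.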

Results

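RNA sequencing was carried out on embryonic mouse cortex in 2 experiments about the long noncoding RNA Lockd, a study that by its title concerns cell cycle progression of cortical progenitors. Cells electroporated with a control plasmid gave 12805874 and 14357950 counts, and cells electroporated with a Lockd shRNA plasmid gave 13401208 and 15911118. Wild-type cortices gave 39334429 and 47460020 counts and PlyA-KI cortices 39282886 and 35167646. Replicates of a group differed by more than sampling noise. Over genes, the chi-square per gene between replicates was 12.5 in control, 17.0 in shRNA, 14 in wild type and 25.4 in PlyA-KI, where sampling alone gives 1. Log2 CPM (counts scaled to the library total) of replicates correlated at 0.9894, 0.9904, 0.9965 and 0.9936 across genes. The knockdown libraries were not closer within a group than between groups: control 1 and shRNA 1 differed by 9.5 and correlated at 0.9914, and over all pairs of a control and an shRNA library these values ran from 9.5 to 20.9 and from 0.986 to 0.9914. Pairs of a wild-type and a PlyA-KI library differed by 26.8 to 49.4 and correlated at 0.9917 to 0.9951, the highest for wild type 1 and PlyA-KI 2.

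The first comparison asked what knocking down Lockd does to gene expression in cells electroporated at E14.5 and sorted at E16.5. Lockd, a long noncoding RNA gene (Entrez 381822; chromosome 6, 134929092 to 134951718, GRCm38), was at 8.90 and 7.80 CPM in the control libraries and at 4.85 and 2.83 CPM in the shRNA libraries, from 114, 112, 65 and 45 counts. Its mean was 8.35 ± 0.779 CPM (SD, n = 2) in control and 3.84 ± 1.43 CPM (SD, n = 2) in shRNA. In the shRNA libraries the lists of S phase and of G2 and M phase genes fell, as did markers of intermediate progenitors and oligodendrocyte precursors, while genes of synapses and axons, upper-layer neurons and p53 targets rose. All of these list calls were lost with an estimated correlation, with adjusted p from 0.29 to 0.34. That form also missed a shifted list of independent simulated genes, so the loss alone does not show that members are correlated.

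The log2 fold change of Lockd was −1.11 (SE 0.30), which did not pass over all genes (adjusted p = 0.254, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and passed when adjusted over the list alone (adjusted p = 0.039). Without shRNA 1 its log2 fold change was −1.54, and without shRNA 2 it was −0.77. Across the 11 alternatives that gave an adjusted p, that p ranged from 0.0162 to 0.512. The gene was called by 2 of them, 1 of which was a fit that leaves out a library.

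Cdkn1b, which encodes the CDK inhibitor p27 and lies next to Lockd (Entrez 12576; chromosome 6, 134920401 to 134925525), was at 343 ± 33.8 CPM in control and 332 ± 19.8 CPM in shRNA (SD, n = 2 each). Its log2 fold change of −0.03 (SE 0.14) was within the spread between replicates (adjusted p = 0.999, edgeR), and turned positive without control 2 (0.09) and without shRNA 1 (0.03). Of the 14 locus genes tested, 3 were higher and 11 lower, with a median log2 fold change of −0.09, and camera did not call the list (adjusted p = 0.199). Lockd alone passed when adjusted over the list alone, and 0 locus genes passed over all genes in edgeR. In DESeq2 0 passed, but 5 of them, Lockd among them, were given no adjusted p. Without Lockd the list had a median of −0.08 and was not called either (adjusted p = 0.561, camera). The other members lay at −0.14 for Gpr19, 0.20 for Crebl2, −0.10 for Dusp16, −0.08 for Borcs5, −0.40 for Mansc1, −0.13 for Lrp6, −0.05 for Etv6, −0.47 for Apold1, 0.02 for Ddx47, −0.04 for Hebp1, −0.50 for Emp1 and 0.56 for Grin2b, none past the threshold. Leaving out a library moved Emp1 to −0.77 (shRNA 1) or −0.23 (control 1) and Grin2b to 0.13 (control 2) or 1.19 (control 1).

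**Figure D1:**
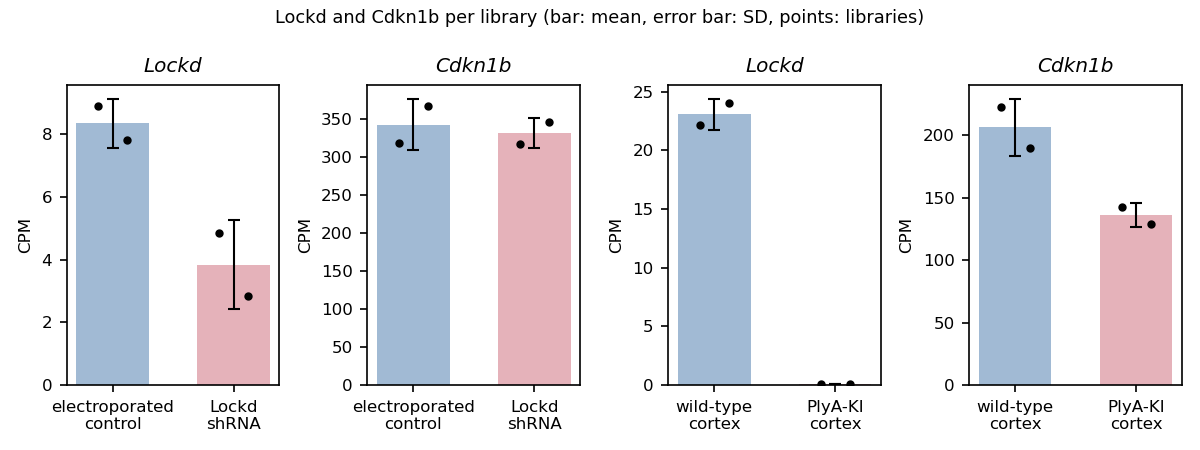
Level of Lockd and Cdkn1b in CPM (vertical axis, from 0) in each group of both experiments; bars are means of 2 libraries, error bars SD and points single libraries. Lockd averaged 8.35 CPM in control, 3.84 in shRNA, 23.1 in wild type and 0.0794 in PlyA-KI, and Cdkn1b 343, 332, 206 and 136.

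All 55 tested G2 and M phase genes were lower in the shRNA libraries, with a median log2 fold change of −0.58, and the list fell by camera (adjusted p = 1.03e-55, adjusted p = 0.33 with an estimated correlation). Over all genes 0 of them passed in edgeR and 11 in DESeq2, and 45 passed when adjusted over the list alone. Ube2c, an E2 enzyme of mitotic cyclin destruction, lay at −0.79 (SE 0.15), and Bub1, a spindle checkpoint kinase, at −0.87 (SE 0.17). All 49 S phase genes were lower too (median −0.50, camera adjusted p = 1.43e-39, adjusted p = 0.29 with an estimated correlation). Of these, 32 passed when adjusted over the list alone, and over all genes 0 in edgeR and 4 in DESeq2. Cdca7 lay at −0.94 (SE 0.15) and Rrm2, a subunit of ribonucleotide reductase, at −0.75 (SE 0.13).

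Among cyclins and CDKs, 20 of 25 were lower (median −0.38, camera adjusted p = 1.93e-09, adjusted p = 0.29 with an estimated correlation), and 11 passed when adjusted over the list alone, against 0 in edgeR and 2 in DESeq2 over all genes. Ccna2 lay at −0.65 (SE 0.14) and Ccnb1 at −0.69 (SE 0.15). Of the D-type cyclins, Ccnd1 was at −0.54 (SE 0.15) and Ccnd2 at −0.46 (SE 0.14), each with an adjusted p of 0.0244 over the list alone, and Ccnd3 at 0.10. The E-type cyclins Ccne1 and Ccne2 lay at −0.38 and −0.42. Among the 6 CDK inhibitors tested, 3 were higher and 3 lower (median 0.05, camera adjusted p = 0.332). Cdkn1a, which encodes p21, was at 10.7 CPM in control and 18.9 CPM in shRNA. Its log2 fold change of 0.84 (SE 0.21) passed when adjusted over the list alone (0.00868) and not over all genes (edgeR adjusted p = 0.229). It was 0.63 without shRNA 1 and 1.03 without shRNA 2. The others were Cdkn1c at 0.26 (0.10 without shRNA 1, 0.41 without shRNA 2), Cdkn2c at −0.50, Cdkn2d at 0.13 and Cdkn3 at −0.08.

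Markers of intermediate progenitors, the dividing cells between radial glia and neurons, were lower for 20 of 22 genes (median −0.40, camera adjusted p = 5.11e-13, adjusted p = 0.33 with an estimated correlation). When adjusted over the list alone 12 passed, and over all genes 0 in edgeR and 1, Chd7, in DESeq2. Chd7, a chromatin remodeller, lay at −0.59 (SE 0.13) and Mfap4 at −0.53 (SE 0.13). Radial glia markers were lower for 26 of 32 genes, by less (median −0.15, camera adjusted p = 3.28e-05, adjusted p = 0.34 with an estimated correlation), and only Prom1, at −0.58 (SE 0.14), passed when adjusted over the list alone, with 0 over all genes in edgeR or DESeq2. Pax6, a transcription factor of radial glia, lay at −0.39. Without shRNA 2 the radial glia call was lost (median −0.09, adjusted p = 0.075 by camera), and without shRNA 1 the median was −0.25. All 5 tested markers of oligodendrocyte precursors were lower (median −0.73, camera adjusted p = 9e-07, adjusted p = 0.33 with an estimated correlation), and 4 passed over the list alone, 0 over all genes in edgeR, and 0 in DESeq2, which gave 2 of the 5, Pdgfra among them, no adjusted p. The 4 were the receptor gene Pdgfra at −1.29 (SE 0.33), Olig2 at −0.86 (SE 0.22), Egfr at −0.70 (SE 0.19) and Olig1 at −0.73 (SE 0.27).

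Genes of synapses and axons were higher in the shRNA libraries for 28 of 33 members (median 0.30, camera adjusted p = 9.7e-12, adjusted p = 0.29 with an estimated correlation). Over all genes edgeR called 0 and DESeq2 1, Shank1, and over the list alone 5 passed, among them Shank1 (0.69, SE 0.14), a postsynaptic scaffold, Syn1 (0.51, SE 0.13), a synaptic vesicle protein, Camk2b (0.86) and Dlg4 (0.40). Upper-layer markers were higher for 12 of 16 genes (median 0.27, camera adjusted p = 1.54e-05, adjusted p = 0.33 with an estimated correlation). The list had Mef2c at 0.80 (SE 0.16) and Inhba at 1.34 (SE 0.41) past the threshold over the list alone, and over all genes 0 in edgeR and 1, Mef2c, in DESeq2. Newborn and migrating neuron genes were higher for 18 of 30 (median 0.15, camera adjusted p = 0.0126, adjusted p = 0.40 with an estimated correlation). Stmn2 (0.53, SE 0.13), Mapt (0.53, SE 0.13) and Ina (0.59, SE 0.16), which encode cytoskeletal proteins of neurons, passed over the list alone, and over all genes 0 in edgeR and 1, Stmn2, in DESeq2. That list was not called without control 1 (median 0.09, adjusted p = 0.649 by camera) or without shRNA 2 (median 0.04, adjusted p = 0.419). Deep-layer markers were split, 9 higher and 8 lower (median 0.02, camera adjusted p = 0.263); Ldb2, at 0.85 (SE 0.22), passed over the list alone, 0 over all genes in edgeR or DESeq2 (1 member had no adjusted p in DESeq2). Targets of p53 were higher for 21 of 26 (median 0.33, camera adjusted p = 1.93e-06, adjusted p = 0.34 with an estimated correlation). Of these Cdkn1a passed over the list alone and 0 over all genes in edgeR or DESeq2 (8 members, Phlda3 among them, had no adjusted p in DESeq2), while Phlda3 lay at 1.04 (SE 0.34) and missed it (0.0579), with 0.54 without shRNA 1 and 1.42 without shRNA 2; without shRNA 1 the median was 0.19.

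The interferon response list was lower for 29 of 31 genes (median −0.53, camera adjusted p = 1.13e-10, adjusted p = 0.51 with an estimated correlation). The 5 members past the threshold over the list alone, with 0 in edgeR and 3 in DESeq2 over all genes (20 members had no adjusted p in DESeq2), belong to antigen presentation by major histocompatibility complex class I. These were B2m (−1.09, SE 0.17), H2-D1 (−1.04, SE 0.17) and H2-K1 (−0.89, SE 0.17), which encode its subunits, Tap1 (−1.03, SE 0.28), which encodes a peptide transporter, and Psmb8 (−1.33, SE 0.39), which encodes a proteasome subunit. B2m went from 73.9 ± 5.04 CPM in control to 34.5 ± 7.17 CPM in shRNA (SD, n = 2 each). The list was not called without control 1 (median −0.05, adjusted p = 0.118 by camera); its median was −0.17 without shRNA 2, −0.85 without control 2 and −0.92 without shRNA 1.

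Cytosolic ribosomal protein genes were lower for 73 of 77, by little (median −0.13, camera adjusted p = 8.63e-06, adjusted p = 0.67 with an estimated correlation), and in edgeR 0 passed over the list alone or over all genes, with 1 at an unadjusted p under 0.05. That gene, Rpl10, lay at −0.56 (SE 0.13) and was called by DESeq2. Without shRNA 2 their median was 0.01 (adjusted p = 0.846 by camera) and without control 1 it was −0.09 (adjusted p = 0.0619), while without shRNA 1 it was −0.28. Microglia and macrophage markers, which a sort for GFP would leave out, were higher for 14 of 21 (median 0.34, camera adjusted p = 0.0486, adjusted p = 0.73 with an estimated correlation), with 0 past either adjustment in edgeR, 1 at an unadjusted p under 0.05, P2ry12 (1.46, SE 0.61, from 0.76 without shRNA 2 to 2.46 without control 1), and 0 in DESeq2, which gave 19 of the 21 no adjusted p, P2ry12 included. Their median was −0.39, called in the opposite direction, without control 2 (adjusted p = 0.00087 by camera), 1.69 without control 1, and 0.01 without shRNA 2 (adjusted p = 0.557).

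Camera called none of the remaining lists. Over all genes 0 of their members passed in edgeR and 1, Fn1, in DESeq2. Medians and camera adjusted p were −0.03 and 0.444 for cortical patterning, −0.14 and 0.0957 for the Notch pathway, and −0.18 and 0.0957 for Wnt pathway targets. Stress lists lay at −0.05 (0.962) for immediate early and heat shock genes, −0.12 (0.181) for the unfolded protein and integrated stress response, and −0.04 (0.405) for hypoxia and glycolysis. Cholesterol synthesis lay at 0.09 (0.158), neural splicing regulators at −0.02 (0.917), histone genes at −0.27 (0.0702), mitochondrially encoded genes at 0 (0.752) and sex-linked genes at 0.06 (0.48). Among other cell types, interneuron and ganglionic eminence markers lay at −0.11 (0.1), Cajal-Retzius markers at 0.04 (0.613), endothelium at −0.14 (0.752), and pericytes, fibroblasts and meninges at 0 (0.745). Members past the threshold over the list alone included Olig2 among interneuron genes, and Fn1 (0.63, SE 0.13) and Pdgfra among pericyte and fibroblast genes, in opposite directions. Median, mean and test differed in sign for splicing regulators (median and mean below 0, test upward), immediate early genes (mean 0.003), Cajal-Retzius (mean −0.02), sex-linked genes (mean −0.01) and the pericyte list (mean −0.11, test upward). Choroid plexus (3 members tested, median 0.22), erythroid (4, median 0.11) and diencephalic markers (2, median −0.06) were too few to test.

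Over all 13758 genes edgeR called 0. At an unadjusted p under 0.05 there were 1033 genes, 462 higher and 571 lower, where 688 arise with no effect; DESeq2 called 49 (17 higher, 32 lower), with no adjusted p for 3468 genes, and limma-trend on FPKM called 0. The smallest adjusted p was 0.143. The 10 genes with the smallest p, none past the threshold (adjusted p 0.143 to 0.166 by edgeR), were B2m, H2-D1, H2-K1, the S phase genes Cdca7 and Rrm2, Ube2c, Aspm (−0.84) and Stil (−1.02) of mitotic spindles and centrioles, Zfp367 (−0.93), and 1 higher gene, Clstn2 (0.87, SE 0.15), which encodes a synaptic adhesion protein. Without control 1 edgeR called 133 genes, without control 2 18, without shRNA 1 85 and without shRNA 2 73. These fits called more genes than the main fit, so a call in them is no support for a gene. Over them B2m ranged from −1.31 to −0.89, H2-D1 from −1.30 to −0.83 and Cdca7 from −1.03 to −0.85.

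**Figure D2:**
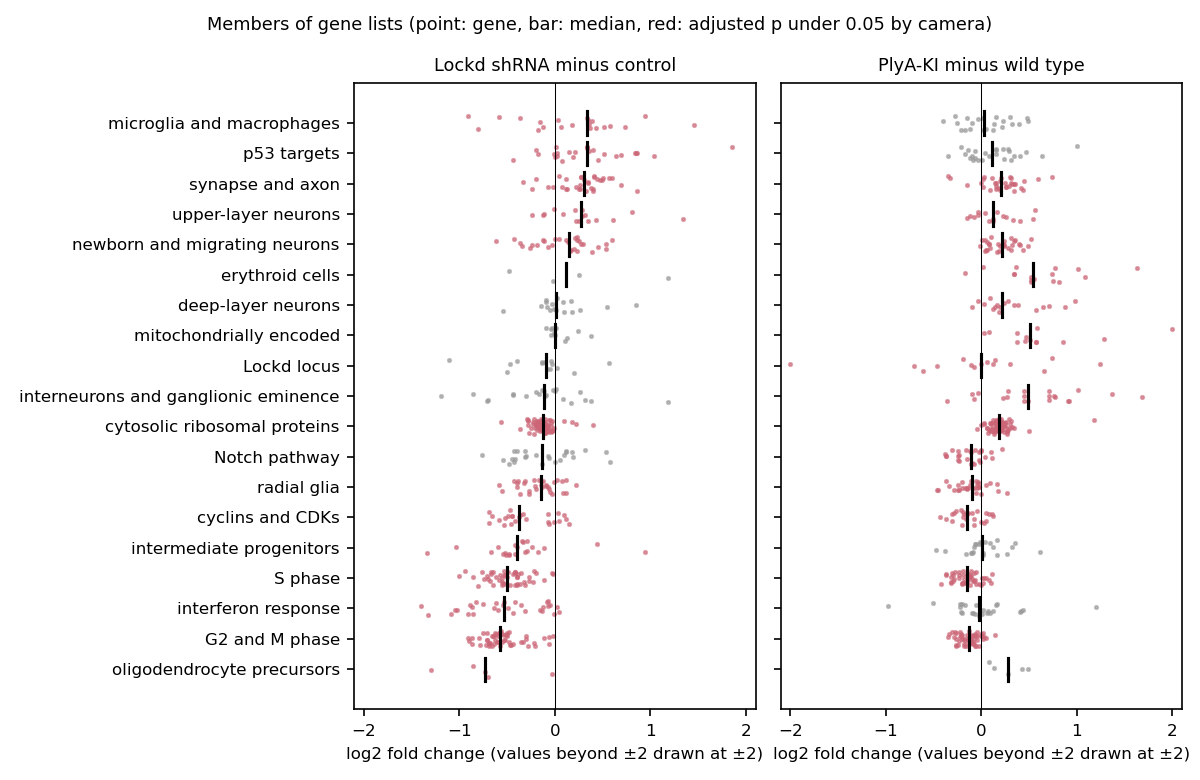
Log2 fold changes (horizontal axis) of the members of gene lists called in either experiment, for Lockd shRNA minus control and PlyA-KI minus wild type; points are genes (values beyond ±2 drawn at ±2), black bars medians, and red marks an adjusted p under 0.05 by camera. Medians of G2 and M phase genes were −0.58 in the knockdown and −0.13 in the knock-in, and those of ribosomal protein genes −0.13 and 0.19.

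The second comparison asked how E13.5 cortices of PlyA-KI embryos differ from wild type. Lockd had 871 and 1139 counts in the wild-type libraries and 4 and 2 in the PlyA-KI libraries, or 23.1 ± 1.31 CPM against 0.0794 ± 0.0318 CPM (SD, n = 2 each), and fell (edgeR adjusted p = 2.98e-07). By summed counts the wild-type level was 287 times that of PlyA-KI (95% exact interval 132 to 784, counting error only). Its neighbour Cdkn1b, at 206 ± 22.9 CPM in wild type and 136 ± 9.64 CPM in PlyA-KI (SD, n = 2 each), had a log2 fold change of −0.61 (SE 0.09). Mitochondrially encoded, ribosomal protein and erythroid genes and several neuronal lists rose, and S phase, G2 and M phase, radial glia and Notch pathway genes fell, in list tests that were all lost with an estimated correlation (adjusted p 0.47 to 0.69).

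Cdkn1b missed the threshold over all genes (adjusted p = 0.0843, edgeR) and passed over the locus list alone (0.000452) and over the CDK inhibitors alone (0.000361). Its log2 fold change was −0.49 without wild type 1, −0.72 without wild type 2, −0.68 without PlyA-KI 1 and −0.55 without PlyA-KI 2. In all, 7 of 12 alternatives called Cdkn1b. Of these, 4 were fits that leave out a library, which called more genes in general than the main fit and so are no support for a call. The largest adjusted p was 0.292 (edgeR), in one fit of all 8 libraries. Of the 15 locus genes tested, 7 were higher and 8 lower (median −0.01, mean −0.47), and camera called the list as lower (adjusted p = 4.49e-07, adjusted p = 0.47 with an estimated correlation). That call rests on Lockd: without it the other 14 had a median of 0.02, a mean of 0.08 and a test downward, and were not called (adjusted p = 0.541, camera). The median with Lockd was −0.02 without wild type 1, 0 without wild type 2, 0.04 without PlyA-KI 1 and −0.06 without PlyA-KI 2. Lockd passed over all genes in edgeR, Lockd and Cdkn1b in DESeq2, and Lockd, Cdkn1b and Apold1 (−0.71, SE 0.21; 0.0406) passed over the list alone. Not past either threshold were Gpr19 (0.30), Crebl2 (0.14), Dusp16 (−0.19), Borcs5 (0.12), Mansc1 (−0.47), Lrp6 (−0.07), Etv6 (−0.11), Ddx47 (−0.01), Gprc5a (1.24), Hebp1 (0.66), Emp1 (0.05) and Grin2b (0.74).

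**Figure D3:**
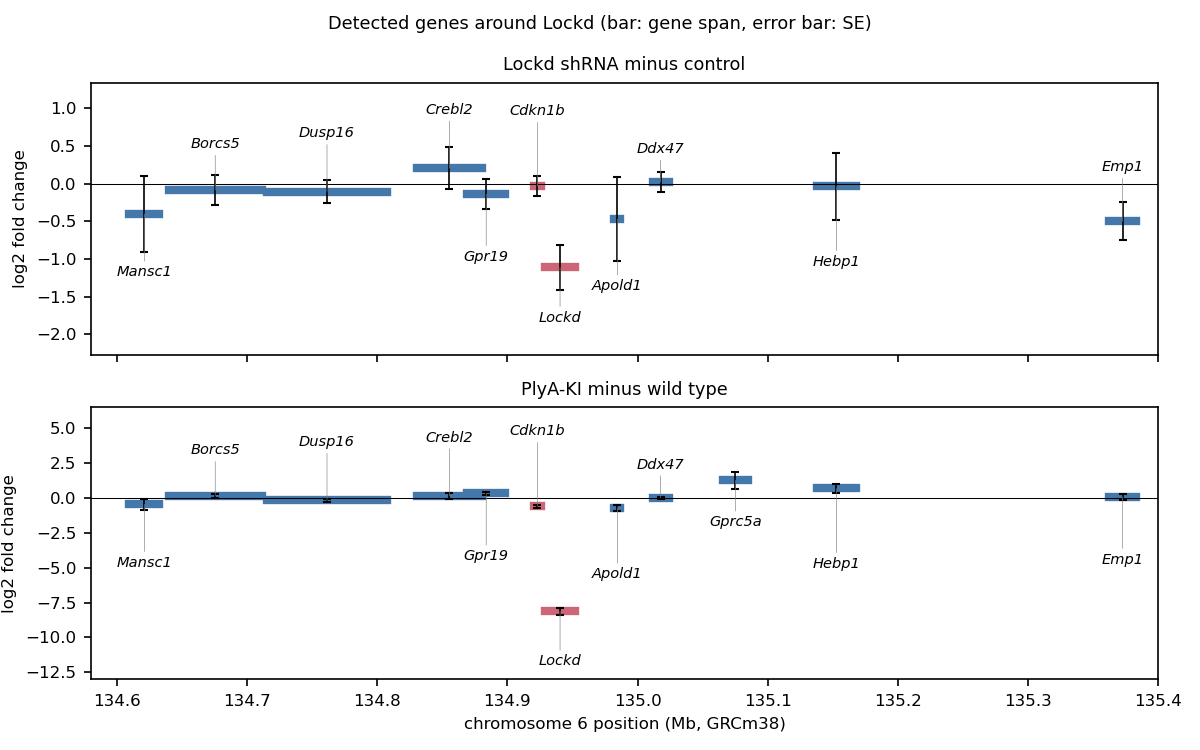
Log2 fold changes (vertical axes, of different ranges) of detected genes around Lockd on chromosome 6 (horizontal axis, Mb, GRCm38) in the knockdown (top) and the knock-in (bottom); bars span each gene, error bars are SE, and Lockd and Cdkn1b are in red. Lockd lay at −1.11 and −8.12, and Cdkn1b at −0.03 and −0.61.

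Over 15398 genes edgeR called 8, 7 higher and 1 lower. The lower gene was Lockd (log2 fold change −8.12, SE 0.26). ND3, which encodes a subunit of respiratory complex I on the mitochondrial genome, rose from 9 and 13 to 316 and 253 counts (4.88, SE 0.29, adjusted p = 7.33e-05). Erdr1, on the X chromosome, rose from 14 and 7 to 326 and 646 counts (5.75, SE 0.49, adjusted p = 0.00094). Leaving out wild type 1 or PlyA-KI 2 moved Erdr1 to 6.46 and 5.05. Mid1, which encodes a ubiquitin ligase bound to microtubules (X chromosome, 169685199 to 169990798), rose from 27.1 ± 1.28 to 59.1 ± 3.15 CPM (1.11, SE 0.09, adjusted p = 0.000797; SD, n = 2 each). G530011O06Rik (X chromosome, 169975043 to 169978917) lies within the span of Mid1 and rose too (3.01, SE 0.21, adjusted p = 0.00027); it was named after its values were seen. Alas2, the erythroid enzyme that starts haem synthesis, rose from 9.59 ± 0.993 to 19.5 ± 0.547 CPM (1.01, SE 0.13, adjusted p = 0.0229). The remaining 2 calls were identifiers without a name (log2 fold change 1.55 each), also given after their values were seen. Values of ND3, Erdr1 and G530011O06Rik are uncertain. Of the 50-base windows of ND3, 98% also occur in nuclear transcripts, Erdr1 is annotated as a transcribed pseudogene, and G530011O06Rik overlaps Mid1.

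**Figure D4:**
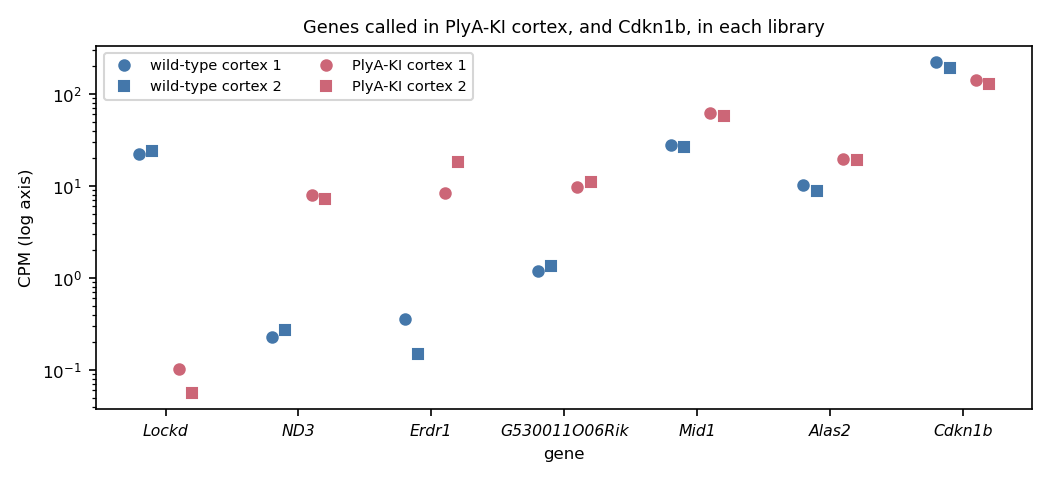
Level in CPM (log axis) of the named genes called in PlyA-KI cortex, and of Cdkn1b, in each library; circles and squares are replicates 1 and 2, blue wild type and red PlyA-KI. ND3, Erdr1, G530011O06Rik, Mid1 and Alas2 are higher in both PlyA-KI libraries than in both wild-type libraries, and Lockd and Cdkn1b lower.

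All 8 calls were kept under each alternative except one fit of all 8 libraries, which lost Mid1, Alas2 and both unnamed identifiers. The number of calls depended on the libraries: 376 without wild type 1, 48 without wild type 2, 133 without PlyA-KI 1 and 565 without PlyA-KI 2. DESeq2 called 116 (65 higher, 51 lower), with no adjusted p for 2687 genes, and 1921 genes had an unadjusted p under 0.05, where 770 arise with no effect. PlyA-KI 1 differed from the other cortex libraries in sex-linked genes, with 38 counts of Xist and 14054 counts of 4 Y-linked genes, against 98720 to 128098 and 0 to 8 in the others. Sex-linked genes (2 tested) were too few for a list test.

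Mitochondrially encoded genes were higher in PlyA-KI for all 13 members (median 0.51, camera adjusted p = 6.77e-19, adjusted p = 0.47 with an estimated correlation). In wild type, ATP6, ATP8, COX2, COX3, ND3 and ND4L lay at 0.722 to 8.9 CPM per kilobase. The other members lay at 880 to 5690. Of the sequence windows of these low genes except ATP8, 98 to 100% also occur in nuclear transcripts, so their values are uncertain. The higher members, COX1, CYTB, ND1, ND2, ND4, ND5 and ND6, were all called by DESeq2, at log2 fold changes of 0.37 to 0.58. Over all genes 1 member, ND3, passed in edgeR and 8 in DESeq2, and 10 passed over the list alone; ND6 lay at 0.57 (SE 0.08) and ND2 at 0.58 (SE 0.10), both named after their values were seen. Cytosolic ribosomal protein genes were higher for 75 of 77 (median 0.19, camera adjusted p = 1.6e-14, adjusted p = 0.69 with an estimated correlation). Over the list alone 5 passed, among them Rpl34 (0.33, SE 0.08), Rps27 (0.32, SE 0.08), Rpl31 (0.30) and Rps29 (0.30), and over all genes 0 passed in edgeR and 2 in DESeq2, and the median was 0.08 without PlyA-KI 2. Erythroid genes were higher for 15 of 16 (median 0.54, camera adjusted p = 3.3e-09, adjusted p = 0.61 with an estimated correlation). Over all genes 1 member, Alas2, passed in edgeR and 1 in DESeq2, and 7 passed over the list alone; the embryonic haemoglobin gene Hbb-bh1, named after its values were seen, lay at 1.08 (SE 0.27). The erythroid median was 0.81 without PlyA-KI 1, the male library, and 0.22 without PlyA-KI 2.

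S phase genes were lower for 42 of 49, by little (median −0.15, camera adjusted p = 4.31e-09, adjusted p = 0.69 with an estimated correlation), and E2f8 (−0.37, SE 0.08), Uhrf1 (−0.37, SE 0.09) and Cdt1 (−0.42, SE 0.10), genes of replication and its control, passed over the list alone, and over all genes 0 in edgeR and 1 in DESeq2. G2 and M phase genes were lower for 49 of 55 (median −0.13, camera adjusted p = 1.02e-08, adjusted p = 0.69 with an estimated correlation), with 0 past either adjustment in edgeR and 16 at an unadjusted p under 0.05, all lower. Plk1, at −0.34 (SE 0.08), was the 1 member called by DESeq2, and Gtse1 lay at −0.34 (SE 0.09). S phase and G2 and M phase medians were −0.04 and −0.03 without wild type 2 and −0.06 and −0.05 without PlyA-KI 1. They were −0.25 and −0.20 without wild type 1, and −0.25 and −0.22 without PlyA-KI 2. The estimated correlation between members was 0.894 for S phase and 0.781 for G2 and M phase genes, far above the preset of 0.01. Cyclins and CDKs were lower for 19 of 25 (median −0.16, camera adjusted p = 3.36e-05, adjusted p = 0.69 with an estimated correlation, median −0.06 without wild type 2 and −0.07 without PlyA-KI 1). Ccnd1 (−0.43, SE 0.09), E2f8, E2f7 (−0.28) and E2f2 (−0.31) passed over the list alone, and over all genes 0 in edgeR and 1 in DESeq2. The other cyclins lay at −0.20 for Ccnd2, −0.16 for Ccnd3, −0.31 for Ccne1 and 0.11 for Ccne2. Leaving out a library gave Ccnd2 from −0.41 (PlyA-KI 2) to −0.02 (PlyA-KI 1), Ccnd3 from −0.33 (PlyA-KI 2) to −0.01 (PlyA-KI 1) and Ccne1 from −0.43 (wild type 1) to −0.18 (wild type 2). Apart from Cdkn1b, CDK inhibitors lay at 0.32 for Cdkn1a, 0.27 for Cdkn1c, −0.12 for Cdkn2c, 0.01 for Cdkn2d and 0.26 for Cdkn3 (6 tested, 4 higher; median 0.14 and test downward, camera adjusted p = 0.713).

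Radial glia markers were lower for 27 of 32 genes (median −0.10, camera adjusted p = 9.31e-05, adjusted p = 0.54 with an estimated correlation). Over all genes 0 passed in edgeR and 3 in DESeq2 (Nes, Notch1 and Gli3), and 5 passed over the list alone. They were Nes (−0.47, SE 0.09), an intermediate filament gene of progenitors, Notch1 (−0.38, SE 0.08), Gli3 (−0.34, SE 0.07), Nr2e1 (−0.29, SE 0.07) and, higher, Fabp7 (0.27, SE 0.08). Notch pathway genes were lower for 22 of 26 (median −0.10, camera adjusted p = 9.31e-05, adjusted p = 0.47 with an estimated correlation), and Notch1, Notch3 (−0.31) and Dtx4 (−0.37) passed over the list alone, with 0 in edgeR and 1 in DESeq2 over all genes. The median was −0.16 without wild type 2. Intermediate progenitor markers were split, 11 higher and 11 lower (median 0.003, mean 0.03, test downward, camera adjusted p = 0.717), and Chd7 (−0.38, SE 0.08) and Sstr2 (−0.47, SE 0.13) passed over the list alone, with 0 in edgeR and 2 in DESeq2 over all genes. Sstr2 lay at −0.28 without PlyA-KI 2 and −0.71 without PlyA-KI 1.

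Newborn and migrating neuron genes were higher for 29 of 30 (median 0.21, camera adjusted p = 1.31e-07, adjusted p = 0.69 with an estimated correlation). Neurod6 (0.52, SE 0.10), a neuronal transcription factor, Gap43 (0.41, SE 0.09), a growth cone protein gene, and Stmn2 (0.34, SE 0.08) passed over the list alone and, in DESeq2, over all genes, where edgeR called 0. The median was 0.09 without wild type 2 and 0.09 without PlyA-KI 1. Deep-layer markers were higher for 16 of 18 (median 0.22, camera adjusted p = 1.91e-07, adjusted p = 0.54 with an estimated correlation, median 0.33 without wild type 1), with Ldb2 (0.64, SE 0.11), Pcp4 (0.57, SE 0.11), Hs3st4 (0.98), Grik3 (0.87) and Lmo3 (0.28) past the threshold over the list alone, with 0 in edgeR and 2 in DESeq2 over all genes. Upper-layer markers were higher for 11 of 16 (median 0.12, camera adjusted p = 0.0437, adjusted p = 0.69 with an estimated correlation), with 2 past it over the list alone, among them Mef2c (0.54, SE 0.10), and over all genes 0 in edgeR and 2 in DESeq2. That call was lost without wild type 2 (median 0, adjusted p = 0.427 by camera) and without PlyA-KI 1 (0.02, 0.505), and the median was 0.25 without wild type 1 and 0.19 without PlyA-KI 2. Synapse and axon genes were higher for 29 of 33 (median 0.21, camera adjusted p = 6.52e-06, adjusted p = 0.69 with an estimated correlation), with 0 past either adjustment in edgeR, 11 at an unadjusted p under 0.05 (10 higher, 1 lower), 0 in DESeq2, Gria1 at 0.59 and Camk2a at −0.35. Their call was lost without wild type 2 (median 0.07, adjusted p = 0.0709 by camera) and without PlyA-KI 1 (0.08, 0.0727), and the median was 0.36 without wild type 1 and 0.33 without PlyA-KI 2. Interneuron and ganglionic eminence markers were higher for 17 of 21 (median 0.49, camera adjusted p = 5.17e-06, adjusted p = 0.69 with an estimated correlation), with 0 past either adjustment in edgeR, 8 at an unadjusted p under 0.05, 0 in DESeq2, and Lhx6, a transcription factor of interneurons, at 1.36 (SE 0.37; 0.83 without wild type 2, 2.14 without wild type 1). Their median was 0.26 without wild type 2 and 0.88 without wild type 1.

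The other lists were not called by camera. Over all genes 0 of their members passed in edgeR, while DESeq2 called 2 Wnt targets and 1 member each of the cortical patterning, p53 and pericyte lists. Medians and camera adjusted p were −0.15 and 0.274 for cortical patterning, −0.12 and 0.383 for Wnt pathway targets, 0.12 and 0.201 for p53 targets, −0.03 and 0.717 for the interferon response, and 0.04 and 0.383 for immediate early and heat shock genes. The unfolded protein and integrated stress response lay at 0.01 (0.727), hypoxia and glycolysis at −0.02 (0.717), cholesterol synthesis at −0.04 (0.355), neural splicing regulators at 0.07 (0.355) and histone genes at −0.02 (0.727). Cell type markers lay at 0.05 (0.713) for Cajal-Retzius cells, 0.28 (0.587) for oligodendrocyte precursors, 0.03 (0.727) for microglia and macrophages, 0.07 (0.727) for endothelium, 0.35 (0.189) for pericytes, fibroblasts and meninges, and 0.31 (0.138) for choroid plexus. Members past the threshold over the list alone were Rspo3 (0.69) of cortical patterning; Ccnd1, Sfrp1 (−0.35) and Apcdd1 (0.44) of Wnt targets. Further ones were Trp53inp1 (0.47, with 0.26 without wild type 2 and 0.70 without wild type 1), Eda2r (1.00), Plk2 (0.40) and Gtse1 of p53 targets, and Slc2a3 (0.53) and Hk2 (−0.32) of glycolysis. Fn1 (−0.47) of the pericyte list passed too. Median, mean and test differed in sign for Wnt targets (mean 0.06, test downward), the interferon response (mean 0.003), hypoxia (mean 0.04, test upward), histone genes (test upward), and microglia and the unfolded protein response (tests downward). Diencephalic markers (4 tested, median −0.16) were too few to test.

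The third comparison asked whether the 2 experiments respond alike. They differ in strain, stage and cells collected as well as in manipulation, so a difference in response cannot be assigned to the manipulation. No gene was called in both by edgeR, which called 0 in the knockdown. DESeq2 called 6 genes in both, Mef2c, Stmn2 and Arpp21 higher in both, Chd7 and Ticrr lower in both, and Fn1 higher in the knockdown and lower in the knock-in. Across the 13526 genes tested in both, fold changes correlated weakly (r = 0.11, rho = 0.105; genes are not independent replicates). The value of r was 0.003 without PlyA-KI 1, 0.022 without wild type 2, 0.049 without shRNA 1, 0.058 without shRNA 2 and 0.07 without control 1. The interaction called 2 genes, both by edgeR in one fit of all 8 libraries. Lockd fell further in the knock-in (difference 6.98, SE 0.47, adjusted p = 3.1e-05), and Erdr1 lay at 0.50 in the knockdown and 5.75 in the knock-in (difference −5.24, SE 0.54, adjusted p = 0.00226). The count of interaction calls was 8 without control 2, 8 without PlyA-KI 2 and 4 without shRNA 1. For Cdkn1b the difference between the experiments (0.58, SE 0.17) was not called (adjusted p = 0.593).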

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

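Of the tests in this part, the list tests of the difference between the experiments, the comparison with radial glia, both tests on blood and all 3 tests on ND3 and the genes at the end of the X chromosome were chosen only after the result was seen. The third pattern weighed below was also picked after its values were seen, in place of a shared direction of change in the 2 experiments.

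Between the experiments, Lockd differed by 6.98 (SE 0.47; adjusted p = 3.1e-05) and Erdr1 by −5.24 (SE 0.54; adjusted p = 0.00226), knockdown minus knock-in in log2 and edgeR with Benjamini-Hochberg adjustment. Medians over each list's genes of the difference per gene (knockdown minus knock-in, log2, with the camera adjusted p of the interaction) were −0.33 (5.21e-13) for S phase genes, −0.44 (7.4e-22) for G2 and M phase genes, −0.12 (0.0246) for cyclins and CDKs and −0.36 (3.08e-08) for intermediate progenitor markers. They were −0.60 (1.15e-07) for mitochondrially encoded genes, −0.30 (3.8e-16) for ribosomal protein genes, −0.59 (0.000168) for the interferon response, −0.63 (5.51e-05) for interneuron markers and −1.12 (0.0431) for oligodendrocyte precursors. The Lockd locus lay at 0.03 (0.0431), a call that rests on Lockd, since without it the median was −0.01 (0.712). Others were deep-layer markers at −0.17 (0.0431), p53 targets at 0.11 (0.0431) and cholesterol synthesis at 0.12 (0.0431). The sex-linked list was called as well (2.64e-05); its median is left out because Y-linked genes had 0 counts in both wild-type libraries and 14054 in PlyA-KI 1. All of these list calls were lost with an estimated correlation, with adjusted p from 0.43 to 0.54. Strain, stage and cells collected differ between the experiments too, so these differences cannot be assigned to the manipulation.

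S phase and G2 and M phase genes were lower in Lockd shRNA than in control cells, with a median log2 fold change of −0.54 over 104 members. A trend with transcript length, GC content or level could shift such lists, but the residual after these was −0.52 (SE 0.02 over genes). A single deviant library is argued against by the median nearest 0 among fits that leave out a library, −0.44 without shRNA 2. Fewer progenitors among the sorted cells may also lower both lists. Radial glia markers, at a median of −0.15, lay 0.39 (SE 0.04 over genes) above the cell cycle genes. A smaller share of progenitors and less cycling per progenitor cannot be told apart. Both SEs treat genes as independent and do not measure the spread between libraries. That Lockd knockdown itself acts on the cell cycle is a hypothesis these 4 libraries leave open, as is an effect of the hairpin on other transcripts, which was not tested. The list calls were lost with an estimated correlation (adjusted p = 0.29 for S phase and 0.33 for G2 and M phase).

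Ribosomal protein, mitochondrially encoded and erythroid genes were higher in PlyA-KI than in wild-type cortex. Blood in the dissected tissue and other sources cannot be told apart for the erythroid part. There 7 of 7 haemoglobin genes were higher, but some, such as Hbb-bh1, belong to that list, and they rose by only 175 CPM (SE 105) in sum. Hbb-b1, outside the list, lay at 0.72 (adjusted p = 0.00126 by DESeq2, 0.155 by edgeR). Ribosomal protein genes rose by 4163 CPM (SE 2620), with a median of 0.19 (0.08 to 0.27 when a library is left out). Blood with as much ribosomal protein as haemoglobin RNA would give at most 0.017 (haemoglobin rise plus 2 SE). That argues against blood of such a make-up for the ribosomal part, but the make-up of blood RNA was not measured. For ribosomal protein genes alone a trend with length, GC content or level was tested. It is argued against by a residual of 0.20, near the median of 0.19 before. Its SE of 0.016 is over genes taken as independent and does not measure the spread between libraries. For all 3 lists the male library is argued against by a smallest share kept without it of 1.12. Without PlyA-KI 2 the erythroid median was 0.22 and the ribosomal median 0.08, so the size of both may rest largely on that library. Differences in stage, dissection or growth between the embryos were not tested, an effect of the allele stays a hypothesis, and the calls were lost with an estimated correlation (adjusted p = 0.47 to 0.69).

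ND3 of the mitochondrial genome and Erdr1, Mid1 and G530011O06Rik of the X chromosome were higher in PlyA-KI cortex. More mitochondrial RNA in general is argued against by ND3 lying 4.4 above the median of the other 12 mitochondrial genes, the highest of which was at 1.28. Reads shared with a nuclear copy, together with a mitochondrial sequence difference between the mice, might explain ND3. Of its 50-base windows, 98% occur in nuclear transcripts, with the most in Gm28438. Its level per kilobase in wild type was 0.0234% of that of ND1, although 4 other genes with such windows lay at 0.02 to 1.28. The male library is argued against for the X chromosome genes by a smallest share kept without it of 0.96. A difference between the mice in copy number or sequence at this end of the X chromosome was not tested, and an effect of the allele on these genes stays a hypothesis.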

How the results depend on the processing

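Without the filter on low counts edgeR called 184 genes in the knockdown and 484 in the knock-in; the log2 fold change of Lockd in the knockdown was −1.10 and that of Cdkn1b in the knock-in −0.62, both called. One fit of all 8 libraries called 53 and 4 genes. DESeq2 called 49 and 116 genes, including Cdkn1b in the knock-in (−0.61), and 25 interaction genes. Across 12 alternatives the adjusted p of Cdkn1b in the knock-in ranged from 5.19e-30 to 0.292.

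The replicate number was fitted as a block because samples of 2 groups carry the same numbers, which is all they share, and there are only 2 pairs per experiment. Across genes, the deviation of replicate 1 from the mean of its group correlated between the groups at 0.179 in the knockdown and 0.101 in the knock-in. With the block edgeR called 161 genes in the knockdown, 2193 in the knock-in, with Cdkn1b at −0.61, and 61 interaction genes; the cause of these higher counts was not tested.

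With an estimated correlation camera called 0 lists in the knockdown and 0 in the knock-in, and fry called 0 and 0. In each case 27 list calls were lost. The loss did not depend on a high estimate. It was −0.003 for cyclins and CDKs in the knockdown and −0.018 for the Notch pathway in the knock-in, below the preset of 0.01. For S phase genes in the knock-in it was 0.894. On simulated counts a list that was truly shifted was missed by the estimated form too, so the lost calls do not show that the lists are unchanged. Nor do the simulations show that the calls with the preset hold. Their genes were drawn independently, and where members are correlated the preset form gives too small a p.

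Fits that leave out a library assume that the library left alone in its group varies like the others. In both experiments they called more genes than the main fit, so a call in such a fit is no support for a gene. Calls ranged from 18 to 133 genes and from 10 to 22 lists in the knockdown, from 48 to 565 genes in the knock-in, and from 2 to 8 genes for the interaction. The median of microglia markers in the knockdown ranged from −0.39 to 1.69 and that of ribosomal protein genes from −0.28 to 0.009. The correlation of fold changes ranged from 0.003 to 0.127, and was 0.174 among genes of at least 5 CPM.

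In the knockdown, leaving out a library gave log2 fold changes from −1.54 to −0.77 for Lockd, −0.13 to 0.09 for Cdkn1b, −0.34 to 0.09 for Gpr19, −0.30 to 0.11 for Borcs5, −0.81 to 0.21 for Mansc1, −0.22 to 0.09 for Etv6, −0.89 to 0.11 for Apold1, −0.02 to 0.06 for Ddx47 and −0.29 to 0.28 for Hebp1. Ranges were −0.17 to 0.39 for Cdkn2d, −0.57 to 0.31 for Cdkn3, −0.05 to 0.24 for Ccnd3 −0.51 to −0.23 for Ccne1 and −0.73 to 0 for Ccne2. Dusp16 (−0.17 to −0.04) and Lrp6 (−0.23 to −0.04) moved without a change of sign. Other genes that changed sign were En2 (−0.55 to 0.68), ND3 (−0.24 to 1.43), COX3 (−0.54 to 0.77) and Eif2s3y (−0.57 to 0.66).

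In the knock-in the ranges were −0.72 to −0.49 for Cdkn1b, −0.03 to 0.29 for Crebl2, −0.07 to 0.05 for Ddx47, −0.38 to 0.39 for Emp1, 0.35 to 1.23 for Grin2b, −0.05 to 0.61 for Cdkn1a, −0.09 to 0.11 for Cdkn2d and −0.03 to 0.24 for Ccne2. Pdgfra (−0.83 to 1.18), Egfr (−0.57 to 1.03), Tcf7l2 (−0.27 to 0.03) and Xist (−11.5 to 0.02) changed sign too. Moves without a change of sign were seen for Gpr19 (0.14 to 0.44), Dusp16 (−0.27 to −0.12), Mansc1 (−0.82 to −0.03), Lrp6 (−0.12 to −0.02), Gprc5a (0.61 to 1.69), Hebp1 (0.42 to 0.95), Cdkn1c (0.13 to 0.42), Cdkn3 (0.10 to 0.41) and Gria1 (0.35 to 0.85), and Borcs5 ranged from 0 to 0.25. With limma-trend on FPKM the knock-in value of Ddx47 was 0 with either pseudocount.

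For the remaining genes and lists named, DESeq2 size factors left 194 results alike and weakened 1, the CPM filter 189 and 1, and a minimum log2 fold change of 1 left 168 alike. On log2(FPKM + 1) 177 were alike, 2 weaker and 1 reversed; on log2(FPKM + 0.1) 178, 1 and 1. DESeq2 made 37 stronger and 1 weaker, dropping the filter 66 stronger, and the fit of all 8 libraries 17 stronger and 4 weaker. The replicate block left 119 alike and made 75 stronger and 1 weaker. Alternatives for the interaction, the correlation and the overlap were added after the data were seen.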

Other observations

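The overlap tests here were chosen only after the result was seen. Genes at an unadjusted p under 0.05 in both experiments included neuronal genes that were higher in both, such as Mef2c (0.80 in the knockdown, 0.54 in the knock-in), Stmn2 (0.53, 0.34), Arpp21 (0.83, 0.60), Ldb2 (0.85, 0.64) and Ptpro (0.78, 0.46). Genes lower in both included Chd7 (−0.59, −0.38), Incenp (−0.56, −0.35) of the chromosomal passenger complex, Ticrr (−0.81, −0.37), a replication initiation factor, and Uhrf1 (−0.56, −0.37). Opposite directions were seen for Fn1 (0.63, −0.47) and Dtx4 (0.58, −0.37), and for Neurod4 (−1.34, 0.35) and Arrdc3 (−0.71, 0.26). By edgeR 0 of these passed over all genes in either experiment, and DESeq2 called Mef2c, Stmn2, Arpp21, Chd7, Ticrr and Fn1 in both.

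At that p, 105 genes were higher in both experiments where 30.5 are expected, and 118 lower in both where 36.8 are expected. Opposite directions were fewer than expected, with 12 genes against 29.5 (higher in the knockdown) and 22 against 38 (lower in the knockdown). Genes of the same direction numbered 3.31 times the expected count, a ratio that was 2.13 without control 1 and 5.11 without wild type 1. Leaving out the members of all lists, 174 genes had the same direction where 52.7 are expected. The expected counts treat genes as independent, and genes outside the lists, such as Incenp and Ticrr, can move together with list members. An excess over them therefore does not by itself show a shared response. Over 12954 genes the correlation of fold changes was 0.112 before and 0.13 after splines on length, GC content and level. It was 0.003 without PlyA-KI 1 and 0.022 without wild type 2 over all genes tested in both.

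Erdr1 was at 288 CPM in electroporated control cells of ICR mice and at 0.252 CPM in wild-type cortex of C57BL/6 mice. In PlyA-KI cortex the genes nearest to it, Mid1 and G530011O06Rik, lay at 1.11 and 3.01, and the more distant Hccs, Arhgap6 and Msl3 at 0.04 (SE 0.09), 1.15 (SE 0.68) and −0.01 (SE 0.09), none of these 3 called by edgeR. Electroporated libraries held both Xist (13423 to 17978 counts) and Y-linked reads (1395 to 3860 counts). Erdr1 was at 0.50 (SE 0.14) in the knockdown, not called (edgeR adjusted p = 0.255).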
